A study of Mus musculus with 18 samples.

How the data were processed

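RNA was measured on 18 Illumina mouse BeadChip arrays of 45281 probes each. The cells were SV40-transformed mouse hepatocytes that lack the aryl hydrocarbon receptor (AhR), a transcription factor activated by ligands such as dioxins. A line that carries the tetracycline repressor alone is called AhR-null, and a line that carries the repressor and an epitope-tagged mouse AhR is called reconstituted. Each line was treated for 8 h in 3 ways: adherent with 0.1% DMSO, adherent with 10 µM YH439, an AhR ligand, or held in suspension in 1.68% methylcellulose. Cells were kept at 34 °C with 10% serum and 100 nM dexamethasone, and 500 ng of RNA was labelled per array. Each of the 6 groups had 3 arrays. The labels call these biological triplicates without saying that they were separate cultures, so the p-values measure the spread between these samples, which may be technical. The suspended cells had also been trypsinised and held in methylcellulose, while their controls were adherent in DMSO. No DMSO is recorded for the suspended cells or for the cells with YH439, so whether either matched its controls in DMSO is not known.

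Per the labels, the authors read the arrays with BeadStudio, whose version is not given in the sources used here. The authors' table of non-normalized values holds the background-subtracted bead intensity of each probe on each array, with a detection p-value beside it. The deposited series matrix holds the authors' processed intensity of the same 18 arrays. Set against the non-normalized intensity, the rank correlation of each matrix column with its own array was at least 0.99896. The matrix values are linear, not centred by gene, have a floor of 20 and run in the direction of the signal. The scaling method between the arrays stays unknown. Every column of the matrix had a median of 20, the floor.

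The main values were made with limma 3.58.1 in R 4.3.3. The function neqc corrected the background by normexp with the negative controls inferred from the detection p-values, added an offset of 16, normalized between arrays by quantiles and took log2. Probes with a detection p-value under 0.05 on at least 3 of the 18 arrays were kept (22203 of 45281). Of all probes, 34885 named 1 gene, 18 named several and 10378 named none. Gene names came from a probe annotation separate from the authors' values. Of the named probes, 34807 were found by gene identifier in a RefSeq table of assembly GRCm38.p6, which was used for names only and changed 0 symbols. Of the kept probes, 18673 named 1 gene, and 3530 that named none or several were left out of the tests by gene. The kept probe with the highest mean stood for its gene, which left 11149 genes, of which 4775 had more than 1 kept probe. The signal over background and the number of arrays limit the precision.

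A mean for each of the 6 groups was fitted over all 18 arrays with lmFit and eBayes (12 residual degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05 for the adjusted p. The comparisons were YH439 and suspension against DMSO in each line, the difference of each response between the lines (reconstituted minus AhR-null), the reconstituted against the AhR-null line under DMSO, and the difference between the YH439 and suspension interactions. Values after ± are standard errors of log2 changes unless SD is stated. A gene detected on no array of 1 group has only a bound. The bound is the mean of the brighter group over the mean, per array of the dimmer group, of the higher of the gene's own signal and the lowest signal among detected probes.

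The genes named in the text followed a rule: Ahr, Cyp1a1, Cyp1b1, Ahrr, Tiparp and Nqo1 in every comparison, the 8 largest rises and 8 largest falls past the threshold whose arrays did not overlap between 2 groups, and up to 4 members of each list with the smallest p. Genes known only by clone or accession names and genes near background in both groups were passed over. A gene named outside the rule was chosen after its values were seen, and this holds for every gene named from a fit with a block, for the added genes of small counts and for genes set side by side between comparisons. The lists were the AhR gene battery, NRF2 targets, SRF and MRTF cytoskeletal targets, YAP and TEAD targets, integrins and focal adhesion, extracellular matrix, TGF-beta targets, immediate-early genes, NF-kB and inflammatory targets, interferon-stimulated genes, hypoxia and glycolysis, ATF4 and unfolded protein response, cholesterol synthesis, mitosis genes, DNA replication genes, p53 targets and glucocorticoid targets. Lists of hepatocyte genes and of mesenchymal and stellate, bile duct, macrophage and endothelial markers served as cell type markers. Some lists share members: of the 13 tested members of the AhR battery, 2 (Nqo1 and Gsta1) are also on the NRF2 list and count in both tests. The 22 lists, the comparisons, the rule and the alternatives in the next paragraph that are not described as added were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, with an estimated correlation beside it, and with fry. The adjustment was over the 22 lists of a comparison. In every list past the threshold, the median, the mean and the camera direction had the same sign. Among the other lists these signs differed for 3 lists under YH439 in the reconstituted cells (YAP and TEAD, extracellular matrix, cholesterol) and for 2 in the AhR-null cells (NF-kB, endothelial). They differed for 6 lists under suspension in the reconstituted cells (YAP and TEAD, TGF-beta, cholesterol, mesenchymal, bile duct, macrophage) and for 4 in the AhR-null cells (YAP and TEAD, hepatocyte, mesenchymal, macrophage). In the difference of the YH439 responses they differed for 5 lists (YAP and TEAD, mitosis, DNA replication, glucocorticoid, macrophage), and in that of the suspension responses for 5 (extracellular matrix, DNA replication, hepatocyte, macrophage, endothelial). They differed for 6 lists between the lines under DMSO (YAP and TEAD, immediate-early, mitosis, DNA replication, macrophage, endothelial) and for 6 between the interactions (extracellular matrix, TGF-beta, NF-kB, ATF4, DNA replication, endothelial).

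The alternatives were normexp by maximum likelihood with an offset of 50, no background correction, median scaling, the authors' processed values, no filter or a stricter filter on dim probes (detection p-value under 0.01 on all 3 arrays of a group), every probe tested alone, eBayes with an intensity trend and robust variances, only the groups compared, a replicate block and each array left out in turn. Whether equal replicate numbers pair the arrays was checked on the deviations of arrays from their group means. Within a line, all 18 pairs of same-numbered arrays had r above 0.1 (0.174 to 0.864, mean 0.568). Between lines, 3 of 27 did (-0.696 to 0.194). Of the 36 pairs of one line with different numbers, 8 did (mean -0.244), among them all 6 pairs of AhR-null replicates 1 and 2 (0.547 to 0.687). Centring on 3 arrays moves these 2 together where replicate 3 stands apart, as it did in the AhR-null groups, so they do not tell number from array set, described below. Pairs of different lines in 1 set had r of -0.683 to 0.542 (7 of 12 above 0.1, mean 0.131). Pairing by number within a line is therefore an assumption, and whether the set adds to the correlation stays open. A replicate block within each cell line was added after this was seen, beside the replicate block across lines, with which YH439 in the reconstituted cells called 19 genes. The results call the added fit the fit with the block. It cannot be applied to the lines under DMSO, since each number then belongs to 1 line. The files used here name no BeadChip, so a block of BeadChips was not run. In its place, 3 sets of 6, 7 and 5 arrays were inferred, after the data were seen, from the 19548 probes detected on no array (mean r between arrays -0.0113 within a set and -0.0791 between sets). The number of 3 sets was imposed on the clustering. Set 1 held replicates 1 and 2 of the AhR-null groups. Set 2 held replicates 2 and 3 of the reconstituted groups and AhR-null DMSO replicate 3. Set 3 held reconstituted replicate 1 of each treatment and replicate 3 of AhR-null YH439 and suspension. Fits with the set as a block, within sets 1 and 2 and without the 6 dimmest arrays were added. Sets 1 and 2 are the only ones that hold more than 1 array of a group.

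The fits were tested on simulated data of 11149 genes in which 200 genes were changed, with noise shared within a replicate number. Of genes changed by 1 log2 unit, 70% were recovered for YH439 in the reconstituted cells, 76% for YH439 in the AhR-null cells, 79% and 81% for suspension in the reconstituted and AhR-null cells, 51% and 57% for the differences of the YH439 and suspension responses, 79% for the lines under DMSO and 45% for the difference of the interactions. Of genes changed by 0.5 log2 units, the same 8 comparisons recovered 25%, 34%, 22%, 23%, 6%, 4%, 32% and 4%. The simulation gave every group the same spread. Between arrays of a group, the SD of log2 differences was 0.49 to 0.596 for AhR-null pairs with replicate 3. It was 0.19 to 0.222 for the other AhR-null pairs and 0.197 to 0.324 for reconstituted pairs. Recovery in the AhR-null cells may therefore be overstated. With the block, 95% and 85% of 1-unit changes were recovered for YH439 in the reconstituted cells and for the difference of the YH439 responses. In the comparison of the lines under DMSO, 20 of 131 simulated calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome was used, so no gene positions are given.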

Results

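Transcript levels were measured in AhR-null and AhR-reconstituted mouse hepatocytes after 8 h with DMSO, with the AhR ligand YH439 or in suspension, with 3 arrays in each of the 6 groups. The series title sets xenobiotics against loss of adhesion as drivers of AhR outcomes. Between 42% and 44.6% of the 45281 probes were detected per array. The median signal lay between 6.03 and 11.9. The 6 dimmest arrays were replicate 3 of the AhR-null groups (6.58 with DMSO, 6.03 with YH439, 6.15 in suspension) and replicate 1 of the reconstituted groups (6.59, 7.19 and 6.97). The other 12 arrays lay between 8.78 and 11.9. Of 33 hepatocyte genes on the array, 8 were detected on all 18 arrays and 17 on none, among them Alb, Apoa1, Ttr and Cps1, which encode albumin, an apolipoprotein, transthyretin and a urea cycle enzyme. Of 19 mesenchymal and stellate cell markers, 14 were detected on all arrays and 4 on none. The numbers detected on all arrays and on none were 2 and 3 of 9 bile duct markers, 3 and 9 of 14 macrophage markers and 2 and 4 of 14 endothelial markers. Ahr itself (probe ILMN_2737460) was detected on 1 of the 18 arrays, an AhR-null array with DMSO. Where this probe lies relative to the introduced coding sequence is not known, so it does not check the reconstitution.

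YH439 raised a small set of genes in the reconstituted cells, the comparison that asks what the ligand does where AhR is present (3 arrays per group). Aldh3a1 (probe ILMN_1253178), an aldehyde dehydrogenase of the AhR battery, rose 4.87-fold (log2 2.28 ± 0.14, adjusted p = 4.88e-07). Tiparp (ILMN_2589291), an ADP-ribosyltransferase that restrains AhR, rose 2.78-fold (1.47 ± 0.19, adjusted p = 0.00159). Chil1, a chitinase-like secreted protein, rose 3.63-fold (1.86 ± 0.22), Adh7, an alcohol dehydrogenase that acts on retinol, 3.08-fold (1.62 ± 0.24), and Ccno, cyclin O, 3.04-fold (1.60 ± 0.19). Chil1 was detected on 2 of the 3 DMSO arrays, near background, so the size of its rise is uncertain. Scn3a, a sodium channel subunit, rose 2.57-fold (1.36 ± 0.15), Gsdme, a pore-forming gasdermin, 2.02-fold (1.01 ± 0.10), and Gpc1, a heparan sulfate proteoglycan, 1.84-fold (0.88 ± 0.13). In all, 15 of 11149 genes changed, 14 higher and 1 lower, and 7 of them by at least 2-fold. Of all 11149 genes, 967 (8.67%) had arrays that did not overlap between the groups, against 10% if the arrays were interchangeable. Same-numbered arrays of a line deviated together, which lowers the share expected by chance within a line. The 10% is therefore too high a reference there, and the share in the AhR-null cells was 4.07%. Among the other genes of the 15, Nfe2l2, which encodes NRF2, rose by log2 0.51 (adjusted p = 0.0243). Ccn4, a matricellular protein, fell by 0.54 ± 0.09 (adjusted p = 0.0144), and its call was lost without reconstituted DMSO replicate 1 (adjusted p = 0.102) or 2 (0.0908) or reconstituted YH439 replicate 2 (0.0676) or 3 (0.127). Median scaling ended the calls of Scn3a (adjusted p = 0.0511), Gpc1 (0.0887) and Ccn4 (0.0662), and within array set 2 those of Scn3a (0.0811) and Ccn4 (0.314) were lost, as was that of Ccn4 with only the groups compared (0.208) and without the 6 dimmest arrays (0.0579); the ranges over the alternatives were 3.02e-05 to 0.0811, 5.74e-06 to 0.0887 and 0.0017 to 0.314. Of 13 tested members of the AhR gene battery, 3 rose over all genes (Aldh3a1, Tiparp and Nfe2l2) and 9 adjusted over the list alone, and the list shifted up (camera adjusted p = 5.19e-38; adjusted p = 1.17e-05 with an estimated correlation). Cyp1b1 (ILMN_1232716), which oxidises steroids and hydrocarbons, was higher by 1.04 ± 0.27 on each of the 3 same-numbered pairs and did not pass (adjusted p = 0.391). With the block it passed (adjusted p = 4.7e-05, range over the alternatives 2.53e-05 to 1). Nqo1, a quinone reductase, stood at 1.00 ± 0.19 (adjusted p = 0.0546; 4.7e-05 with the block, range 4.7e-05 to 0.4). Ahrr, the AhR repressor, was not well above background with DMSO and stood at least 1.11-fold higher, which did not pass (adjusted p = 1). It passed in none of the other comparisons. Cyp1a1 (ILMN_2613985), the AhR target most often measured, was detected on 0 of 18 arrays, and so were both Cyp1a2 probes.

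Among the other lists, the NRF2 targets shifted up with YH439 in the reconstituted cells (median 0.16, camera adjusted p = 2.54e-09; adjusted p = 0.000599 with an estimated correlation). None of its 22 tested members passed over all genes and 4 rose adjusted over the list alone. The glucocorticoid targets shifted up as well (adjusted p = 1.61e-05; adjusted p = 0.00507 with an estimated correlation), with 0 of 18 members past the threshold over all genes and 4 higher and 1 lower adjusted over the list alone. With the block, 7 members of the AhR battery, 4 NRF2 targets and 3 glucocorticoid targets passed, all higher. The SRF and MRTF targets shifted down with the preset correlation (adjusted p = 0.0362), which was lost with an estimated one (adjusted p = 0.118 with an estimated correlation). The other 18 lists had camera adjusted p between 0.0764 and 0.74; 0 of their members passed over all genes, and adjusted over the list alone 2 ATF4 targets did, both higher. The count of genes was 96 with the block (71 higher, 25 lower), 85 with the inferred array set as a block, 12 within set 2, 39 with the authors' values and 32 without the 6 dimmest arrays. Within set 2 the AhR battery stayed past the threshold (adjusted p = 0.0343 with an estimated correlation) and the NRF2 targets did not with an estimated correlation (adjusted p = 0.49).

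**Figure D1:**
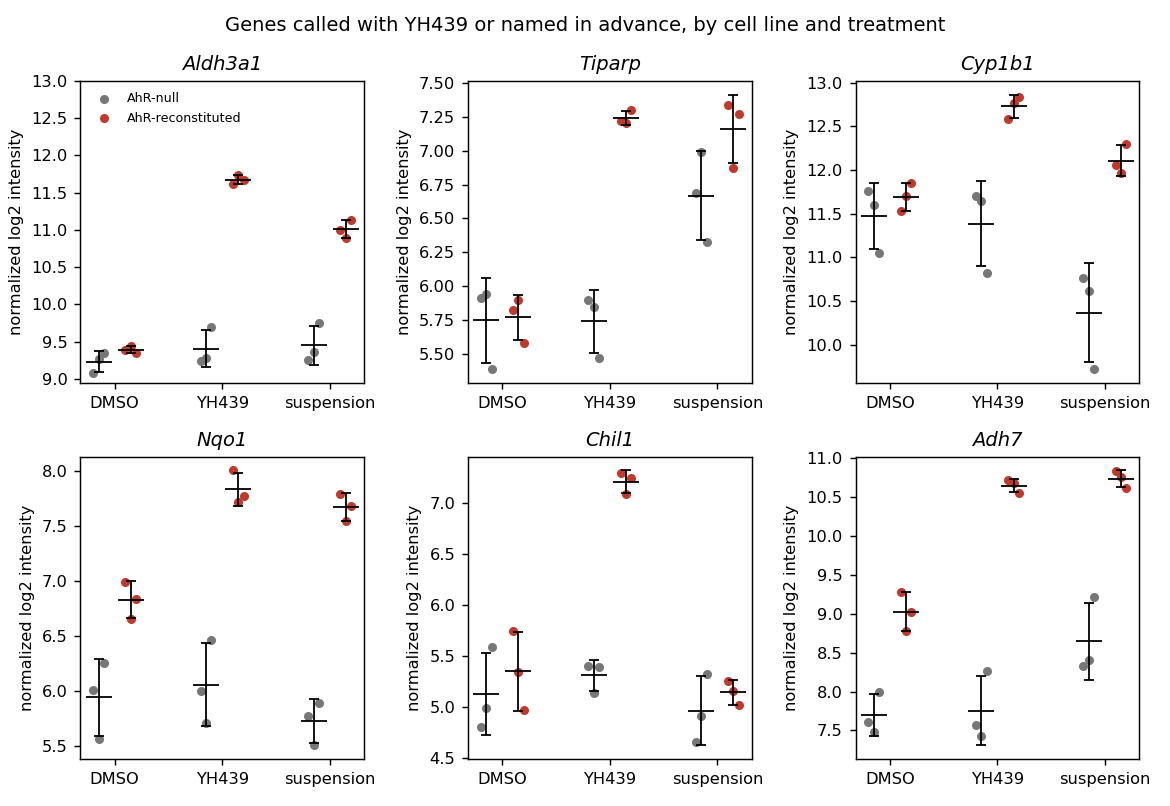
Log2 intensity (vertical axes) of Aldh3a1, Tiparp, Cyp1b1, Nqo1, Chil1 and Adh7 in the 6 groups (horizontal axes), with a point per array and the mean and SD of the 3 arrays as a line and bars. Aldh3a1 rose by log2 2.28 with YH439 in the reconstituted cells and stood 0.18 above its DMSO mean with YH439 in the AhR-null cells.

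In the AhR-null cells, YH439 moved no gene past the threshold, the comparison that shows what the ligand does without AhR. Cyp1b1 stood at log2 -0.08, Tiparp at -0.01 and Nqo1 at 0.11 (each adjusted p = 1), and Ahrr was not well above background in either group. Aldh3a1 stood at 0.18. With limma, 0 genes passed and 185 had an unadjusted p under 0.05, a smaller share of the 11149 genes than the 0.05 expected by chance. With the block 722 did, so the fit without it may be too cautious and its 0 does not show that nothing changed. Arrays of the 2 groups did not overlap for 454 of 11149 genes (4.07%), against 10% if the arrays were interchangeable, which same-numbered arrays were not. With the block, 2 genes passed: Pde4b, a phosphodiesterase of cyclic AMP, was higher by 0.68 ± 0.06 (adjusted p = 0.00238), and Osr1, a zinc finger transcription factor, fell by 0.62 ± 0.08 (adjusted p = 0.0204). Pde4b alone passed with the set as a block (adjusted p = 0.0299) and with the authors' values (0.0445), and 0 genes passed within set 1. The AhR battery did not shift (0 of 13 members passed, also adjusted over the list alone; adjusted p = 0.274). The glucocorticoid targets shifted up here too (adjusted p = 4.49e-05; adjusted p = 0.0148 with an estimated correlation), with 0 of 18 members past the threshold, also adjusted over the list alone. The immediate-early genes passed with the preset correlation (adjusted p = 0.00864) and not otherwise (adjusted p = 0.25 with an estimated correlation). The other 20 lists had adjusted p between 0.0884 and 0.838 and 0 members past the threshold. Across 11149 genes, which are not independent replicates, the YH439 changes of the lines had Pearson r 0.104 and Spearman rho 0.08.

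The YH439 response differed between the lines for 3 genes, each with a larger rise in the reconstituted cells. The difference was 2.11 ± 0.20 on the log2 scale for Aldh3a1 (4.3-fold, adjusted p = 0.000208) and 0.98 ± 0.14 for Gsdme (adjusted p = 0.0107). Scn3a passed as well (adjusted p = 0.0107), but it was detected on 0 AhR-null arrays, so its AhR-null side holds background alone and the size of its difference was not measured. Tiparp differed by 1.48 ± 0.27, Chil1 by 1.68 and Adh7 by 1.56, and they did not pass (adjusted p = 0.12, 0.12 and 0.36). These 3 passed with the block (adjusted p = 0.00367 for Tiparp, with a range of 0.000817 to 0.493 over its alternatives, 0.00612 for Chil1 and 0.00149 for Adh7). Chil1 was detected on 1 of the 3 AhR-null DMSO arrays, so the size of its difference rests in part on background. Cyp1b1 differed by 1.12 ± 0.38 (adjusted p = 1; 0.002 with the block, range 0.00182 to 1) and Nqo1 by 0.89 (adjusted p = 1; 0.00548 with the block, range 0.00548 to 1). With the block, 18 genes passed (29 with normexp by maximum likelihood), all 18 with the larger rise in the reconstituted cells; they included Ptx3, a pentraxin of innate immunity, Gpc1, Foxq1, a forkhead factor (1.12), and Cldnd1 (1.23). The count was 18 with the array set as a block, and no set holds all 4 groups. Of 13 AhR battery members 1 passed, 6 adjusted over the list alone, and the list shifted up in the difference (median 0.48, camera adjusted p = 2.4e-25; adjusted p = 0.000101 with an estimated correlation). The NRF2 targets shifted up as well (median 0.21, adjusted p = 6.03e-06; adjusted p = 0.00471 with an estimated correlation), with 0 of 22 members past the threshold, also adjusted over the list alone. With the array set as a block the AhR battery kept its shift (adjusted p = 1.46e-05 with an estimated correlation), and the NRF2 targets lost theirs (adjusted p = 0.111 with an estimated correlation). Without the 6 dimmest arrays these were 0.00312 and 0.445. The other 20 lists had adjusted p of 0.342 to 0.907, with 0 members past the threshold over all genes and 1 hepatocyte gene lower adjusted over the list alone. Scn3a and Gsdme lost their calls, leaving 1 gene, without AhR-null YH439 replicate 1 (adjusted p = 0.0567 and 0.0584), AhR-null YH439 replicate 2 (0.051 for each) or reconstituted YH439 replicate 1 (0.0551 for each). Scn3a also lost its call with no background correction (adjusted p = 0.0789), median scaling (0.871), only the groups compared (0.107) and without the 6 dimmest arrays (0.053), and Gsdme with only the groups compared (0.07); over all alternatives the ranges were 0.000777 to 0.871 and 0.00062 to 0.07.

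Suspension changed 2692 of 11149 genes in the reconstituted cells (1194 higher, 1498 lower; 3 arrays per group), the comparison that asks what loss of adhesion does where AhR is present. Ndrg1, a hypoxia- and stress-responsive gene, rose 17.6-fold (log2 4.14 ± 0.40), Ddit3, which encodes the stress factor CHOP, 11.4-fold (3.51 ± 0.24), Ankrd37, a hypoxia-inducible gene, 9.83-fold (3.30 ± 0.18), and Trib3, a pseudokinase of the stress response, 8-fold (3.00 ± 0.11). Ciart, a circadian repressor, rose by 3.49 ± 0.20. The placental hormone paralogs Prl2c2, Prl2c3 and Prl2c4 rose by 3.51, 3.49 and 3.45, and their near-identical sequences leave open which of them was measured. The largest falls were in the small proline-rich genes Sprr2j-ps (-2.08 ± 0.18) and Sprr2k (-1.88), also close paralogs, Nxph1, a neurexin ligand (-1.94 ± 0.19), Slc1a3, a glutamate transporter (-1.83 ± 0.21), Taf9b, a transcription cofactor (-1.78 ± 0.09), Mycbp, a MYC-binding protein (-1.76 ± 0.12), Fzd2, a WNT receptor (-1.69 ± 0.19), and Chst13, a chondroitin sulfotransferase (-1.59 ± 0.13). At least 2-fold changes numbered 269 higher and 92 lower. Of all 11149 genes, 5104 (45.8%) had arrays that did not overlap, against 10% if the arrays were interchangeable.

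Of the stress lists, ATF4 and unfolded protein response targets rose almost as a whole in the suspended reconstituted cells, 24 of 27 members over all genes and 25 adjusted over the list alone (camera adjusted p = 1.25e-23; adjusted p = 1.54e-06 with an estimated correlation). Herpud1, a degradation factor of the endoplasmic reticulum, rose by log2 2.53 and Chac1, which breaks down glutathione, by 2.44. Hypoxia and glycolysis genes rose in 17 of 23 members and 20 adjusted over the list alone (adjusted p = 1.51e-19; adjusted p = 2.23e-05 with an estimated correlation), with Egln3, an oxygen-sensing hydroxylase, at 2.88, the glucose transporter Slc2a1 at 2.56 and the angiogenic factor Vegfa at 2.35. Immediate-early genes rose in 12 of 24 members and 16 adjusted over the list alone (adjusted p = 1.03e-09; adjusted p = 0.00268 with an estimated correlation), among them Atf3 (1.92), Fos (1.76) and Ier3 (1.58). NRF2 targets rose in 11 of 22, 11 also adjusted over the list alone (adjusted p = 3.95e-08; adjusted p = 0.00097 with an estimated correlation), with heme oxygenase Hmox1 at 2.67 and the glutathione transferases Gsta1 and Gsta2 at 2.79 and 2.64. The AhR battery rose in 7 of 13 and 11 adjusted over the list alone (adjusted p = 2.69e-08; adjusted p = 0.00466 with an estimated correlation). Of its members, Aldh3a1 rose by 1.62 ± 0.14 (adjusted p = 9.62e-07), Tiparp by 1.39 ± 0.19 (7.52e-05) and Nqo1 by 0.84 (0.00475), and Cyp1b1 stood at 0.42 (0.305; 0.00116 with the block, range 0.00116 to 0.559). The p53 targets rose in 8 and fell in 2 of 18, the same counts adjusted over the list alone (adjusted p = 0.00153; adjusted p = 0.0238 with an estimated correlation, and 0.18 when the block was added to it), with the stress gene Gadd45a up by 2.15 and the sestrin Sesn2 by 1.55, while the sestrin Sesn1 was among the 2 that fell.

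Mitosis genes fell in 12 of 24 members and rose in 1 (13 and 1 adjusted over the list alone) in the same cells, with Cdca3 at -0.89, the centromere histone Cenpa at -0.79 and the spindle kinesin Kif11 at -0.79, while the centrosomal kinase Nek2 rose by 0.94. The list's shift down passed (adjusted p = 0.00153; adjusted p = 0.0496 with an estimated correlation, and 0.202 when the block was added to it). Interferon-stimulated genes fell in 7 of 16 and 8 adjusted over the list alone (adjusted p = 0.0249; adjusted p = 0.129 with an estimated correlation), among them the GTPase Gbp2 (-0.98), Ifi35 (-0.85) and Isg15, a ubiquitin-like protein (-0.80). The other 14 lists did not shift as a whole (adjusted p from 0.0628 to 0.962). In these the numbers that rose and fell were 6 and 2 of 18 glucocorticoid targets (7 and 3 adjusted over the list alone), 1 and 3 of 21 SRF and MRTF targets, 3 and 2 of 19 YAP and TEAD targets, and 1 and 2 of 25 integrin and focal adhesion genes. They were 3 and 5 of 26 extracellular matrix genes (3 and 7 adjusted over the list alone), 3 and 2 of 15 TGF-beta targets, 2 and 4 of 19 NF-kB targets (2 and 5 adjusted over the list alone), 3 and 0 of 17 cholesterol synthesis genes, and 4 and 5 of 31 DNA replication genes (4 and 6 adjusted over the list alone). The cell type markers gave 2 and 1 of 16 hepatocyte genes, 4 and 1 of 14 mesenchymal markers (4 and 2 adjusted over the list alone), 1 and 0 of 6 bile duct, 1 and 0 of 4 macrophage, and 1 and 1 of 6 endothelial markers. Single members moved far: the TGF-beta list's Bhlhe40, a clock-linked repressor, rose by 2.62, the keratin Krt18 by 2.12, the bile duct factor Sox9 by 1.62 and the macrophage receptor Csf1r by 1.35. The myosin light chain Myl9 (-1.33), its kinase Mylk (-1.24), the chemokine Cxcl1 (-1.26), the growth factor Csf1 (-1.15) and the matrix protease Mmp3 (-1.16) fell.

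The count in the suspended reconstituted cells was 5430 with the block (2366 higher, 3064 lower), which included all 2692 genes, 5341 with the array set as a block, 3660 within set 2 and 4302 without the 6 dimmest arrays. With the authors' values 2968 genes passed, and the share that was higher moved from 44.4% to 56.8% (1686 higher, 1282 lower), and with median scaling to 37.1%.

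In the AhR-null cells, suspension changed 2525 genes (1202 higher, 1323 lower; 3 arrays per group), the comparison that shows the response to lost adhesion without AhR. Which direction held the majority depended on the fit: 47.6% were higher here, 54.2% with the authors' values (1556 higher, 1314 lower) and 40.2% with median scaling (940 and 1397), and with only the groups compared 520 were higher and 349 lower. With every probe, 2089 probes were higher and 2081 lower. With 1 array left out in turn, more genes were higher without AhR-null DMSO replicate 3 (1222 and 961), AhR-null suspension replicate 1 (1113 and 1021) or replicate 2 (1061 and 851). Ndrg1 rose 15.3-fold (log2 3.93), Ddit3 14.5-fold (3.86), Ciart by 3.55, Ankrd37 by 3.43, and Prl2c3, Prl2c4 and Prl2c2 by 3.24, 3.20 and 3.18. Smtnl2, a smoothelin-like protein, was not well above background with DMSO and rose at least 6.44-fold. Falls were largest for Sprr2j-ps (-2.08), Tagln, an actin-binding protein (-1.82 ± 0.15), Mycbp (-1.80), Sprr2g (-1.60), Chst13 (-1.60), the stromal membrane protein Cd248 (-1.60 ± 0.12) and Spon2, a matrix protein (-1.59 ± 0.14). Angptl7, an angiopoietin-like protein that was not well above background in suspension, was at least 2.81-fold lower. Among these genes, 262 rose and 79 fell by at least 2-fold. Of all 11149 genes, 3526 (31.6%) had arrays that did not overlap, against 10% if the arrays were interchangeable.

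ATF4 targets rose in 21 of 27 members in the suspended AhR-null cells and 25 adjusted over the list alone (adjusted p = 2.24e-23; adjusted p = 1.76e-06 with an estimated correlation), hypoxia and glycolysis genes in 20 of 23 and 22 (2.24e-23; adjusted p = 8.02e-06 with an estimated correlation), and immediate-early genes in 13 of 24 and 14 (1.26e-08; adjusted p = 0.00591 with an estimated correlation). Examples were Herpud1 (2.55), Chac1 (2.46), Egln3 (2.75), Slc2a1 (2.71), Atf3 (1.83) and Fos (1.73). NRF2 targets rose in 7 and fell in 1 of 22, 9 and 1 adjusted over the list alone (adjusted p = 0.000937; adjusted p = 0.019 with an estimated correlation), with Hmox1 up by 2.22. p53 targets rose in 9 and fell in 1 of 18, as they did adjusted over the list alone (adjusted p = 0.000157; adjusted p = 0.0115 with an estimated correlation, and 0.117 when the block was added to it). Mitosis genes fell in 11 and rose in 1 of 24, 12 and 1 adjusted over the list alone (adjusted p = 0.000724; adjusted p = 0.0381 with an estimated correlation, and 0.145 when the block was added to it). The AhR battery rose in 6 and fell in 1 of 13, the same adjusted over the list alone (adjusted p = 0.00205; adjusted p = 0.079 with an estimated correlation). Of its members, Aldh3a1 stood at 0.22 (adjusted p = 0.309; 0.044 with the block) and Tiparp rose by 0.92 (adjusted p = 0.00242), Cyp1b1 fell by 1.10 ± 0.27 (0.00753), and Nqo1 stood at -0.22 (0.48; 0.0321 with the block, range 0.0321 to 0.869). The SRF and MRTF targets fell in 5 and rose in 1 of 21 (adjusted p = 0.0352; adjusted p = 0.104 with an estimated correlation), with Tagln, Myl9 (-1.25) and Mylk (-1.11) among those that fell. The glucocorticoid targets rose in 6 and fell in 3 of 18, 7 and 3 adjusted over the list alone (adjusted p = 0.0258; adjusted p = 0.079 with an estimated correlation). Neither of these 2 shifts passed within set 1 (adjusted p = 0.0569 for each).

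The other 13 lists did not shift in the suspended AhR-null cells (adjusted p from 0.183 to 0.977). In these the numbers that rose and fell were 3 and 3 of 16 interferon-stimulated genes, with Gbp2 (-0.89) lower and the signalling factor Stat2 (0.44) higher, 2 and 4 of 19 YAP and TEAD targets (2 and 6 adjusted over the list alone), and 1 and 5 of 25 integrin and focal adhesion genes, with talin, Tln1, at -0.72. They were 2 and 5 of 26 extracellular matrix genes, 3 and 2 of 15 TGF-beta targets (3 and 3 adjusted over the list alone), 1 and 5 of 19 NF-kB targets, 1 and 1 of 17 cholesterol genes, and 5 and 4 of 31 DNA replication genes. Markers gave 2 and 1 of 16 for hepatocytes, 4 and 2 of 14 for mesenchymal cells (4 and 3 adjusted over the list alone), 1 and 0 of 6 for bile duct, 1 and 0 of 4 for macrophages and 1 and 1 of 6 for endothelium. Krt18 (1.47), Sox9 (1.56) and Csf1r (1.38) rose in these cells too. The count was 5260 with the block, 5063 with the array set as a block, 4004 within set 1 and 4147 without the 6 dimmest arrays. With only the groups compared it was 869, and the calls of Cyp1b1 (adjusted p = 0.082) and Tiparp (0.0571) ended. The same setting gave 3420 in the reconstituted cells. The main fit shares a variance per gene across both lines. Among DMSO and suspension arrays, the SD of log2 differences was 0.49 to 0.596 for AhR-null pairs with replicate 3. It was 0.195 to 0.222 for the other AhR-null pairs and 0.197 to 0.324 for reconstituted pairs. The main AhR-null count thus rests in part on reconstituted arrays, so the main counts of the lines are not directly comparable.

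The suspension responses of the lines were close to each other. Across 11149 genes, which are not independent replicates and share no arrays here, the log2 changes had Pearson r 0.891 and Spearman rho 0.831. Over the genes called in the reconstituted cells, the slope of the AhR-null change on the reconstituted change was 0.901, and 2660 of 2692 (98.8%) had the same sign. Genes higher in both lines numbered 943 (129 expected if the calls were independent) and genes lower in both 1029 (178 expected). Opposite calls were made for 2 genes, and for 18 of the 4182 genes called in both lines with the block, where the difference itself passed for 7. Among these were Cyp1b1 (0.42 in the reconstituted cells, adjusted p = 0.00116 with the block, and -1.10 in the AhR-null cells, 8.63e-07) and Nqo1 (0.84, 4.09e-06, and -0.22, 0.0321). Serpinb2, a serine protease inhibitor, rose by 0.82 ± 0.19 in the reconstituted cells (adjusted p = 0.00488) and fell by 0.55 ± 0.19 in the AhR-null cells (0.0472). Fam161a, a ciliary protein, was near background in both reconstituted groups (detected on 1 of 3 arrays with DMSO and 0 in suspension), so its fall there was not measured. It was not well above background in the AhR-null cells with DMSO and at least 1.12-fold higher in suspension.

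**Figure D2:**
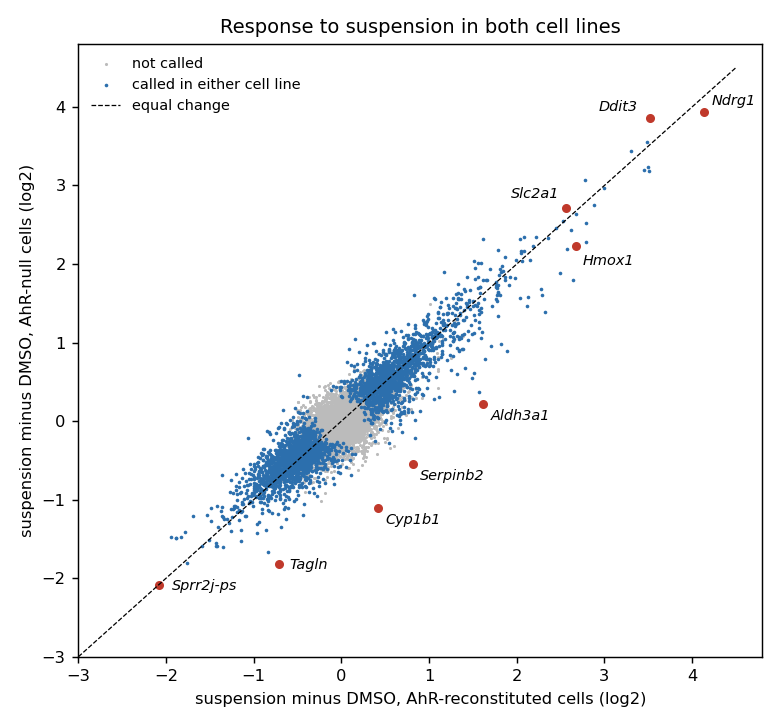
Log2 change with suspension in the AhR-null cells (vertical axis) against that in the reconstituted cells (horizontal axis), with a point per gene for 11149 genes and named genes marked. The changes had Pearson r 0.891 across genes.

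The suspension response differed between the lines for 1 gene, Aldh3a1, with a rise larger by log2 1.40 ± 0.20 in the reconstituted cells (2.64-fold, adjusted p = 0.0395). With limma 292 genes had an unadjusted p under 0.05, a smaller share than the 0.05 expected by chance, and 1231 with the block. The fit without the block may therefore be too cautious here. The call was lost when any of 11 of the 12 arrays was left out (adjusted p 0.0571 to 0.206, log2 1.30 to 1.48), which were AhR-null DMSO replicates 1, 2 and 3, AhR-null suspension 1 and 2, and replicates 1, 2 and 3 of reconstituted DMSO and of reconstituted suspension. It was also lost with no background correction (0.0521), every probe (0.0557) and only the groups compared (0.122), within a range of 0.000121 to 0.206 over its alternatives. In 10 of these leave-outs 0 genes were called, without AhR-null suspension replicate 1 the gene called was Ngef, and without AhR-null suspension replicate 3 there were 5 genes. Tiparp, which rose in both lines, did not pass in this difference, with the block or in any other of its 25 alternatives (lowest adjusted p 0.346, log2 0.301 to 0.652). Cyp1b1 differed by 1.52 ± 0.38 (adjusted p = 0.907; 0.000236 with the block, range 0.000137 to 1) and Nqo1 by 1.06 (0.907; 0.0019 with the block, range 0.0019 to 1). Serpinb2 differed by 1.36 ± 0.27 (adjusted p = 0.251; 0.0204 with the block) and Tagln by 1.11 (0.251; 0.00566). With the block 19 genes passed, 12 higher and 7 lower in the difference (9 genes with no background correction, 14 with median scaling, 21 with the authors' values and 37 with normexp by maximum likelihood), among them the keratin Krt16 (0.94) and Gsta2 (0.84). With the authors' values 9 passed (8 higher, 1 lower; 88.9% higher against 100%), and with the array set as a block 13; no set holds all 4 groups. The AhR battery shifted up in the difference (median 0.25, adjusted p = 4.7e-09; adjusted p = 0.00623 with an estimated correlation), with 1 member past the threshold and 3 adjusted over the list alone. NRF2 targets shifted up (median 0.28, adjusted p = 4.7e-09; adjusted p = 0.00138 with an estimated correlation), with 0 of 22 past the threshold and 2 adjusted over the list alone. The interferon-stimulated genes shifted down (median -0.34, adjusted p = 2.06e-06; adjusted p = 0.00684 with an estimated correlation), with 0 of 16 past the threshold, also adjusted over the list alone. With the array set as a block these 3 lists stood at adjusted p = 0.00119, 0.0149 and 0.0223 with an estimated correlation, and without the 6 dimmest arrays at 0.0508, 0.116 and 0.0964. Hypoxia genes shifted down (adjusted p = 0.013; adjusted p = 0.0839 with an estimated correlation) and SRF and MRTF targets up (0.0155; adjusted p = 0.0839 with an estimated correlation). The other 17 lists had adjusted p of 0.101 to 0.991. Over all genes 0 members of these lists passed, and adjusted over the list alone 1 immediate-early gene, 1 p53 target and 1 hepatocyte gene were lower and 1 SRF target was higher.

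YH439 and suspension were set against each other within the reconstituted cells, the contrast that the series title names. Of the 15 genes changed by YH439, 11 rose in suspension as well (1.5 expected if the calls were independent) and 1, Ptx3, moved the other way (0.86 with YH439 and -0.43 in suspension). Suspended AhR-null cells, with their own controls, also raised Prl2c2 (3.18), Adh7 (0.953), Tiparp (0.921), Ccno (0.795) and Nfe2l2 (0.628). The rest of the 11, Aldh3a1, Gpc1, Gsdme, Spint1, Nckap5 and Scn3a, did not pass there. Ptx3 fell further in those cells (-1.05). Chil1 stood at -0.21 in suspension and did not pass. Across 11149 genes the responses had Pearson r 0.297 and Spearman rho 0.298. They share the DMSO arrays, and simulated unchanged groups gave r 0.5; the covariance was 0.0202 and the simulated one 0.021. The differences of the responses between the lines, which share the same controls, had r 0.48 (simulated 0.501) and covariance 0.0189 (simulated 0.0421). With the block, 5 genes passed in both differences, Ptx3, Cyp1b1, Aldh3a1, Gsdme and Nqo1, against 0.0307 expected. In 100 draws of unchanged groups that shared the DMSO arrays, 0 genes were called in both for either pair. The expected numbers leave out the shared controls and the draws leave out the effects. Neither covariance exceeded its simulated value, but the simulation took the arrays as independent. Same-numbered arrays of a line deviated together, so the simulated covariances may be too high. How much of each excess comes from the shared controls was therefore not decided.

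The difference between the YH439 and suspension interactions, in which the DMSO arrays cancel, called 0 genes with limma. An unadjusted p under 0.05 was found for 319 genes, a smaller share than the 0.05 expected by chance, and for 1193 with the block. The fit without the block may therefore be too cautious here as well. With the block, 18 genes passed (10 higher, 8 lower). These calls depended on the background and scaling: the blocked count was 0 with no background correction, 4 with median scaling, 37 with the authors' values and 55 with normexp by maximum likelihood. With the main values, Chil1 (1.72) and Tiparp (1.01, adjusted p = 0.818; 0.0458 with the block, range 0.0215 to 1) stood on the YH439 side, and so did Aldh3a1 (0.71, adjusted p = 0.989; 0.0442 with the block). Krt18 (-1.04), Il1rn, an interleukin-1 antagonist (-0.94), Krt16 (-0.88) and Tagln (-0.80) stood on the suspension side. Chil1 was detected on 1 of the 3 AhR-null suspension arrays, so its value rests in part on background. Cyp1b1 and Nqo1 passed in none of their 25 alternatives (lowest adjusted p 0.234 and 0.611). The counts were 23 with the array set as a block, 10 with the authors' values and 1 without the 6 dimmest arrays (Slc17a8, a glutamate transporter, 1.27 ± 0.14). The interferon-stimulated genes shifted toward YH439 (median 0.27, adjusted p = 1.67e-05; adjusted p = 0.0273 with an estimated correlation), with 0 of 16 past the threshold, also adjusted over the list alone. That shift stood at adjusted p = 0.0721 with an estimated correlation and the block, 0.0673 with the set as a block and 0.0861 without the 6 dimmest arrays. The AhR battery shifted toward YH439 (0.000591; adjusted p = 0.0779 with an estimated correlation) and the SRF and MRTF targets toward suspension (0.00208; adjusted p = 0.0615 with an estimated correlation). The other 19 lists had adjusted p of 0.0552 to 0.919, and the integrins and focal adhesion genes moved from 0.0552 to 0.0254 with the block (adjusted p = 0.13 with an estimated correlation and the block). Over all genes 0 members of any list passed. Adjusted over the list alone, 3 AhR battery members stood on the YH439 side and 1 SRF target on the suspension side. Of the other lists, the numbers on the YH439 and suspension sides were 1 and 2 for YAP and TEAD targets, 1 and 1 for immediate-early genes, 1 and 0 for p53 and for glucocorticoid targets, and 0 and 1 for extracellular matrix and for hepatocyte genes.

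**Figure D3:**
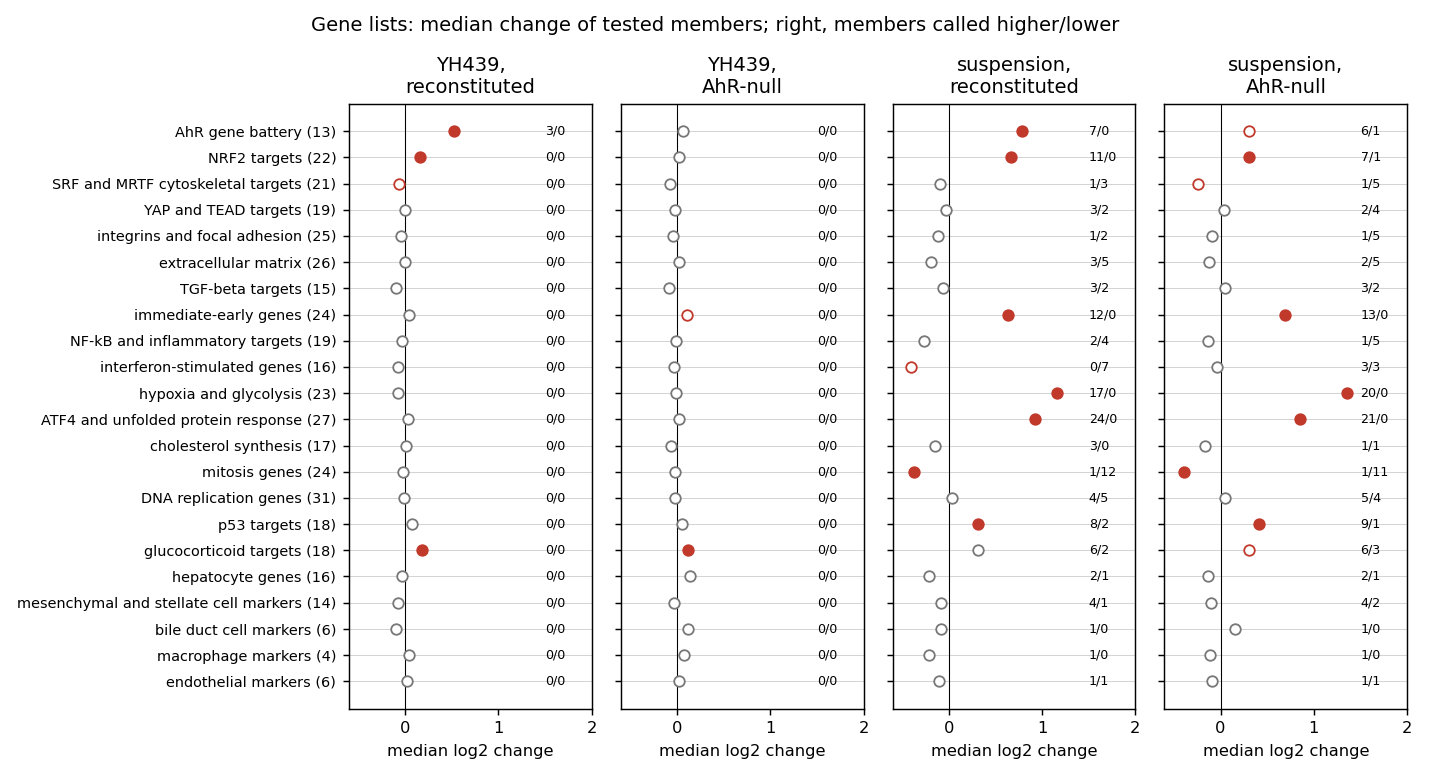
Median log2 change (horizontal axes) of the 22 gene lists (vertical axis) with YH439 and with suspension in each cell line, with the numbers of members that rose and fell beside each point. Filled red points passed camera with a preset and an estimated correlation, open red points with the preset one alone, and grey points with neither.

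Under DMSO, the reconstituted cells differed from the AhR-null cells in 61 genes (10 higher, 51 lower; 3 arrays per group), the comparison that sets the lines side by side without added ligand. AhR-null DMSO replicates 1 and 2 lay in inferred array set 1 and the reconstituted DMSO arrays in sets 2 and 3, so line and set are nearly confounded, and in simulated data 20 of 131 calls of this comparison were false. Adh7 was 2.51-fold higher (log2 1.33 ± 0.24, adjusted p = 0.0137), followed by Sdc3, a syndecan (0.86 ± 0.14), Scx, a tendon transcription factor (0.86), Parm1 (0.68), Cnot6, a deadenylase (0.65), Lrrc8d, an anion channel subunit (0.62), Arhgap10 (0.62) and Tbrg4 (0.57). Slit3, a guidance ligand, was lower (-2.10 ± 0.22, adjusted p = 0.000132), as were Cntnap2, an adhesion protein (-1.46), Adamts9, a matrix protease (-1.40), Mmp3 (-1.32), Greb1 (-1.27), Pcdh10, a protocadherin (-1.26), Capn6 (-1.24) and the interferon-inducible Ifi27l2a (-1.22). Of all 11149 genes, 1469 (13.2%) had arrays that did not overlap, against 10% if the arrays were interchangeable. Cyp1b1, Tiparp and Nqo1 did not pass. Over the alternatives their adjusted p was 0.00118 to 0.992 for Cyp1b1, at least 0.117 for Tiparp and 0.00587 to 0.302 for Nqo1. Their log2 differences ran from 0.00948 to 0.746, from -0.189 to 0.356 and from 0.494 to 1.04. Interferon-stimulated genes were lower in 1 of 16 members, Usp18 (-0.69), and in 3 adjusted over the list alone (adjusted p = 4.75e-05; adjusted p = 0.0374 with an estimated correlation). Mesenchymal markers were lower in 2 of 14, Dcn (-0.81) and Pdgfra (-0.79), with 1 higher and 2 lower adjusted over the list alone (adjusted p = 0.00814; adjusted p = 0.11 with an estimated correlation). Extracellular matrix genes were lower in 1 member, Mmp3 (adjusted p = 0.00305; adjusted p = 0.137 with an estimated correlation). NRF2 targets were higher in 0 of 22 and in 6 adjusted over the list alone (adjusted p = 0.00328; adjusted p = 0.0615 with an estimated correlation), and the AhR battery in 1 of 13, Nfe2l2 (0.47), and in 4 adjusted over the list alone (adjusted p = 0.0137; adjusted p = 0.161 with an estimated correlation). The other 17 lists had adjusted p of 0.0628 to 0.885, and Tagln of the SRF list (-0.71) and Snai2 of the TGF-beta list (-0.63) were their members lower over all genes. Adjusted over the list alone, the numbers higher and lower were 2 and 3 for hepatocyte genes, 2 and 1 for hypoxia genes, 0 and 2 for TGF-beta targets, 1 and 0 for ATF4 and for p53 targets, and 0 and 1 for SRF targets and for macrophage markers.

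The count of 61 between the lines depended on the arrays used. It was 27 without AhR-null DMSO replicate 1, 33 without replicate 2, 77 without replicate 3, 38 without reconstituted DMSO replicate 1 and 26 without replicate 3, 7 with only the groups compared (0 higher), 793 with the array set as a block, 0 within set 2 (2 reconstituted arrays and 1 AhR-null array), 2725 without the 6 dimmest arrays, which sets set 1 against set 2 alone, and 130 with the authors' values (35 higher, 95 lower, or 26.9% higher against 16.4%). Slit3, Cntnap2, Adamts9, Mmp3, Greb1, Pcdh10, Capn6 and Parm1 kept their calls whichever array was left out. Adh7, Sdc3, Scx, Cnot6, Lrrc8d, Arhgap10, Tbrg4 and Ifi27l2a each lost theirs without at least 2 of the 6 DMSO arrays (adjusted p 0.0501 to 0.286). With only the groups compared, Slit3, Cntnap2, Adamts9, Pcdh10 and Capn6 kept their calls, and the others of these did not (adjusted p 0.0774 for Adh7 and Sdc3, 0.0821 for Mmp3, Greb1 and Ifi27l2a, 0.13 for Parm1, and 0.18 to 0.373 for the rest). Cnot6 and Arhgap10 also lost theirs with normexp by maximum likelihood (adjusted p = 0.0546 and 0.111), no background correction (0.0563 and 0.0517), every probe (0.0722 and 0.0652) and trend variances (0.078 and 0.0817). Median scaling ended those of Lrrc8d (0.0662) and Arhgap10 (0.0723), and the authors' values those of Cnot6 (0.175) and Tbrg4 (0.0905). The shift of the interferon-stimulated genes stood at adjusted p = 0.23 with an estimated correlation and the set as a block, 0.85 within set 2 and 0.357 without the 6 dimmest arrays.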

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

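Of the tests in this part, the correlation of same-numbered arrays, the slope between the lines, the AhR battery's p for the difference between the lines, the number of arrays with Cyp1a1 and the splits by line and replicate number were chosen after the results were seen.

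The following results differed between the cell lines by a test of the difference itself. For YH439, the response of the reconstituted cells exceeded that of the AhR-null cells by log2 2.11 for Aldh3a1 and 0.98 for Gsdme, and by a fitted 1.53 for Scn3a, whose AhR-null side was not well above background. The AhR gene battery did so by a median of 0.484 and the NRF2 targets by 0.208, and these lists share 2 tested members, so their shifts are not independent. For suspension, Aldh3a1 differed by 1.40, the AhR battery by a median of 0.25, the NRF2 targets by 0.276 and the interferon-stimulated genes by -0.34. Between YH439 and suspension, the line difference of the interferon-stimulated genes differed by a median of 0.273. Some of these depended on the fit. The suspension call of Aldh3a1 was lost in 11 of 12 leave-outs (adjusted p 0.0571 to 0.206). The Scn3a call was lost with median scaling (adjusted p = 0.871), only the groups compared (0.107), no background correction (0.0789) and without the 6 dimmest arrays (0.053). That of Gsdme was lost with only the groups compared (0.07). Scn3a and Gsdme each also lost their calls in 3 of 12 leave-outs. With an estimated correlation, the shift of the interferon-stimulated genes between YH439 and suspension stood at adjusted p = 0.0721 with the block, 0.0673 with the array set as a block and 0.0861 without the 6 dimmest arrays. The NRF2 shift with YH439 was lost with the set as a block (adjusted p = 0.111) and without the dimmest arrays (0.445), where the 3 list shifts with suspension were lost too (0.0508, 0.116 and 0.0964).

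The splits of the arrays bear on how far these counts stand above a regrouping. Among the 100 splits drawn, 12 gave at least the 3 genes of the YH439 difference (highest other 2735), and 14 at least the 1 gene of the suspension difference (highest other 3131), and by these splits regrouping by chance is not excluded for these 2 counts. The drawn splits ignore the numbers within a line, and so carry differences of line and array set into the interaction. For the difference between the interactions the count was 0, which all 100 splits reach whatever the data (highest other 3979), so the splits say nothing about it. Splits that called over 100 genes numbered 1, 2 and 3. The highest of each comparison set AhR-null replicates 1 and 2 and reconstituted replicate 3 against the other replicates in 1 treatment. The sides were reversed in the other treatment. This grouping mixes the lines and parts reconstituted replicates 2 and 3 of set 2, so it follows neither line nor set alone. Splits that kept arrays of a line and number together, of which there are 10, gave at most 0 genes besides the real ones (3, 1 and 0 genes, or 18, 19 and 18 with the block), and 10 are too few for a share under 0.05. The comparisons of 3 against 3 arrays have 10 splits, also too few. Their real counts and highest others were 15 and 0 for YH439 in the reconstituted cells (1 split with as many), 0 and 1 in the AhR-null cells (10 splits, which a count of 0 fixes), 2692 and 0 for suspension in the reconstituted cells (1 split), 2525 and 0 in the AhR-null cells (1 split) and 61 and 1 for the lines under DMSO (1 split). Of the 10 splits within a line, 4 part all 3 same-numbered pairs, as the real split does, and the others part 1 pair. The highest of the other splits that part all 3 pairs called 0 genes in each treatment comparison, and the 1 gene in the AhR-null cells came from a split that parts 1 pair.

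More genes were called when the replicate number within a line was a block. A candidate explanation is that arrays of a number shared a culture or an array batch: the lowest correlation of deviations between same-numbered arrays of a line was 0.174. The quantile normalization used here is argued against as the source, since the ratio of blocked to unblocked calls for suspension in the reconstituted cells was 2.25 with median scaling and 1.65 with the authors' values. Whether the shared part came from the culture, the RNA or the array stays open, and no biological explanation was tested.

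The suspension response was nearly the same in both lines. A response that mostly needs AhR is argued against by the slope of 0.901 of the AhR-null on the reconstituted change. Within a line, same-numbered arrays lay in 1 set except for AhR-null DMSO replicate 3, so deviations of a set largely cancel in each response. The correlation was 0.885 when reconstituted arrays came from set 2 alone and AhR-null arrays from set 1 alone. Because of that balance, this value adds little against deviations shared through a set. Loss of adhesion, trypsin, methylcellulose and any absence of DMSO go together in both lines, and which of them the shared response follows stays untested.

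Cyp1a1 was below background while other AhR targets rose. With YH439, the AhR battery's shift was larger in the reconstituted cells (adjusted p = 0.000101 with an estimated correlation). AhR status and cell line go together here, and under DMSO the lines differed in 61 genes. Action of YH439 through AhR is therefore not told apart from other differences between the lines. Whether the probe fails to report the transcript cannot be told apart from a transcript below background, since the Cyp1a1 probe was detected on 0 of 18 arrays and no sample with a known level was used here. Its fitted values stood 0.25 ± 0.07 higher with YH439 in the reconstituted cells and at -0.02 in the AhR-null cells, the direction of a reporting probe, but they lie below background and exclude nothing.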

How the results depend on the processing

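The inferred array sets, the fits without the 6 dimmest arrays and the replicate block within each cell line were added after the data were seen; a block of BeadChips was not run, since the files used here name none. The direction of every list that passed was kept under all alternatives run. It was also kept for the passing genes among those named in every comparison or ranked by largest rise or fall. Other named genes were not followed through all alternatives. Of the values for the genes followed, 1151 kept their side of the threshold, 36 passed and 57 no longer passed. With 1 array left out these were 592, 2 and 54. Of the values for gene lists, 1594 kept their side, 38 passed and 40 no longer passed. The correlation of the suspension responses stayed within its spread in all 16 alternatives (4 scalings and 12 leave-outs). That spread was computed from the same 12 leave-outs, which could hardly fall outside it, so only the 4 scalings test it. The block within each cell line kept all genes called without it in the counts of the comparisons. The replicate block across lines moved no count by more than 1.5 times (19, 0, 3, 2844, 2652, 1, 70 and 0 genes) and ended the call of Cnot6 between the lines (adjusted p = 0.0653). No scaling moved the median of all genes by 0.1. Signal over background limits the rise of genes such as Ahrr, Cyp1a1, Scn3a and Chil1.

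Counts below follow the order YH439 in reconstituted and AhR-null cells and their difference, suspension in reconstituted and AhR-null cells and their difference, the lines under DMSO and the difference between the interactions, and only those moved by more than 1.5 times are given. The cause was not tested unless stated. With the authors' values, YH439 called 39, 1 and 5 genes, the suspension difference 9, the lines 130 and the interactions 10. With no background correction the suspension difference called 0. With every probe, which tests more features, suspension called 4349 and 4170 probes and its difference 0. With only the groups compared, the YH439 difference called 1, suspension in AhR-null cells 869, its difference 0 and the lines 7. With the replicate block within each cell line, YH439 called 96, 2 and 18, suspension 5430, 5260 and 19, and the interactions 18. With the array set as a block, YH439 called 85, 1 and 18, suspension 5341, 5063 and 13, the lines 793 and the interactions 23. Array set 1 alone gave 4004 for suspension in AhR-null cells, and array set 2 alone gave 0 for the lines. Without the 6 dimmest arrays, YH439 called 32 in reconstituted cells and 5 in the difference (Aldh3a1, Adh7, Gsdme, Chil1 and Cntn3), suspension 4302, 4147 and 4 (Cyp1b1, Aldh3a1, Cntn3 and Fam161a), the lines 2725 and the interactions 1. With each array left out in turn, the counts ranged from 11 to 13, 0 to 0, 1 to 4, 1956 to 2156, 1912 to 2631, 0 to 5, 26 to 77 and 0 to 0.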

Other observations

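The gene groups in this part were chosen after their values were seen, so their counts describe and do not test them. Of 13 clock genes tested, 5 rose, 0 fell and 8 did not pass with suspension in each line, and 0 changed with YH439 in the reconstituted cells. The 5 that rose were Ciart (log2 3.49 in reconstituted and 3.55 in AhR-null cells), Bhlhe40 (2.62 and 2.43), the nuclear receptors Nr1d1 (1.14 and 1.10) and Rora (1.14 in reconstituted cells, and at least 2.03-fold in AhR-null cells, where it was not well above background with DMSO), and the transcription factor Dbp (0.84 and 0.99). Nr1d2 stood at 1.30 and 1.29 and did not pass (adjusted p = 0.0767 and 0.0813). The period genes Per1, Per2 and Per3, Cry2, Arntl, Clock and Tef did not pass.

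Of 26 genes of the cornified envelope and the keratins, 8 rose and 5 fell with suspension in each line, and 0 changed with YH439 in the reconstituted cells. Involucrin, Ivl, rose by 0.99 and 0.98, the late envelope gene Lce1g by 1.57 and 1.19, Lce1f, which was not well above background with DMSO, at least 1.93-fold and 1.16-fold, and the keratins Krt16 by 2.32 and 1.38, Krt18 by 2.12 and 1.47 and Krt13 by 0.95 and 1.00. The Sprr2 genes e, f, g, j-ps and k fell, and their probes do not separate such close paralogs with certainty. The histone demethylases Kdm3a (2.08 and 2.16) and Kdm4b (1.40 and 1.68) rose in both lines.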
